A study of Cavia porcellus with 24 samples.

How the data were processed

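RNA was measured in knee cartilage and infrapatellar fat pad of Dunkin Hartley guinea pigs of both sexes, 6 months after an intra-articular injection of DPBS, SVF or SVF enriched for CD31+ cells, with 4 libraries per tissue and injection (24 in all). Groups, sexes and replicate numbers were taken from the labels. RNA was extracted with a silica column kit and poly(A) RNA was made into strand-specific libraries, per the labels' protocols, which name 2 library kits without saying which library used which. Reads were checked with FastQC, trimmed with fastp, aligned with STAR 2.7.11a and counted per gene with featureCounts, per the submitters' processing notes, which also name DESeq2 1.38. The genome build, the annotation release and the counting options are not given in the sources used here. The authors deposited 1 table of raw read counts per Ensembl gene, with 18933 genes and 1 column for each library, and all values in the text were computed from these counts.

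Total counts were 72628067 to 107619052 per library, and 17659 to 18588 genes had at least 1 count. Low counts were mostly even: of counts from 1 to 10, 74.5 to 81.7 percent were even in each library, so the counts halved and rounded were run as an alternative. Gene symbols were those of the deposited table, with placeholder symbols replaced where the RefSeq gene table of assembly mCavPor4.1 names the same gene identifier. Of the genes, 5918 had a symbol, and 5075 were left after setting aside 835 placeholder symbols and 8 ambiguous ones. The named genes held 35.6 to 41.1 percent of a library's counts. Genes without a symbol were tested like the others.

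Differential expression was tested with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F tests) in R 4.3.3. Each tissue was fitted on its own 12 libraries with treatment and sex as terms (8 residual degrees of freedom). The tissue contrast and the tissue by treatment interactions came from 1 fit of all 24 libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. CPM are TMM-scaled within a tissue for the treatment comparisons. Positive log2 changes mean higher in the first-named group.

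Gene groups were tested with camera on voom values (limma 3.58.1, preset inter-gene correlation 0.01, Benjamini-Hochberg adjustment over the lists of a comparison), for 23 of 25 lists of joint, adipose, immune, vascular, muscle, marrow and general cell process genes. The lists held 614 genes, of which 175 could be matched by symbol, and lists with fewer than 3 measured members were not tested. Each list was also tested with its correlation estimated from the data, and with fry. Counts of members adjusted over the list alone used Benjamini-Hochberg over the edgeR p-values of the list's members. List scores are mean log2 CPM of the members in a library.

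The rule for naming genes took called genes with a symbol, and where these were few, the 5 higher and 5 lower named genes with the lowest p. For the tissue contrast it took the 10 higher and 10 lower with the largest log2 change, and for interactions up to 5 called genes per direction. Added to these were a fixed set of joint and adipose genes and up to 4 members with the lowest p of each list named. Mpo, Myh2 and Alb are given per library as markers chosen after values were seen.

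Alternatives were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter on low counts, no sex term, male libraries only, a fit by replicate number, and fits without the libraries numbered above 50 in the labels or without each library in turn. Chosen after the data were seen were halved counts, muscle and marrow list scores as covariates, fits without 3 cartilage libraries that stood apart in a principal component analysis (DPBS male replicate 4, SVF female replicate 1 and CD31 female replicate 1), and fits without each library in turn and voom for the 24-library results. Counts of calls were compared with all 35 splits of the 8 libraries of a comparison, or with 100 random regroupings for the 24-library results. Likeness of the SVF and CD31 changes was compared with simulated unchanged groups sharing a reference (20 simulations) and with the DPBS libraries split 2 and 2 (6 splits). The overlap of genes in the same simulations was counted after the data were seen.

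The fits were tested on simulated counts with 200 changed genes per comparison. EdgeR recovered 54 percent of 2-fold and 87 percent of 4-fold changes with 5 false calls for cartilage SVF against DPBS (17260 genes), and DESeq2 made 68 false calls there. For fat pad CD31 against DPBS (16701 genes) edgeR recovered 64 and 88 percent with 4 false calls, and DESeq2 made 46. Another split of the cartilage SVF and DPBS libraries gave 3247 DESeq2 calls, so these rates may not hold for the data. Figures were drawn in Python 3.11.15.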

Results

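RNA-seq was carried out on knee cartilage and on the infrapatellar fat pad, the adipose tissue behind the patellar tendon. The animals were Dunkin Hartley guinea pigs, a strain that develops knee osteoarthritis without surgery. Tissue was taken 6 months after an injection into the joint of the saline vehicle DPBS or of a cell preparation. The preparations were stromal vascular fraction (SVF, the mixed non-adipocyte cells of adipose tissue) and SVF enriched for CD31+ cells, called CD31 here after the endothelial surface protein. Each of the 2 tissues had 4 libraries per injection, 24 in all. The question was how each cell preparation differed from the vehicle and from the other preparation. Each tissue had 2 libraries from females, in cartilage 1 each in the SVF and CD31 groups, and in the fat pad 1 each in the DPBS and SVF groups. Total counts ranged from 72628067 to 107619052 per library. Of 18933 genes, 5075 carried a usable symbol, so gene groups hold the members that could be named. Pecam1, the gene of CD31 itself, and Col1a1, Prg4, Adamts5, Il6, Ccl2 and Lep were not analysed here, because no counted gene carried these symbols. Expression is given as CPM (counts scaled to library size), mean ± SD with n = 4 libraries per group. Log2 changes are given ± an approximate SE, the absolute log2 change divided by the square root of the edgeR F statistic.

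The tissue contrast described what each sample held. In cartilage, Col2a1, the main collagen of hyaline cartilage, stood at 15396 ± 10748 against 95.4 ± 107.6 CPM in the fat pad (n = 12 each, log2 change 7.45 ± 0.60, edgeR with Benjamini-Hochberg adjustment, adjusted p = 9.9e-10). All 6 measured cartilage matrix genes were higher in cartilage. Acan, the aggrecan core protein, was higher by 4.62 log2 units, Col9a3 by 5.42 and Snorc by 8.52. Other genes higher in cartilage were Cytl1 (738 ± 777 against 0.730 ± 0.509 CPM), Serpina3 (634 ± 452 against 1.15 ± 0.822), Clec3a (3542 ± 1892 against 60.0 ± 47.4) and Ecrg4 (786 ± 532 against 17.2 ± 8.32). So were Serpina3k (37.1 ± 53.4 against 0.0732 ± 0.125), Edar (25.3 ± 9.26 against 0.684 ± 0.693) and Tubb1, a tubulin of megakaryocytes and platelets (212 ± 93.9 against 6.97 ± 7.76). In the fat pad, the adipokine Adipoq was higher, at 2710.3 ± 892 CPM after DPBS against 114 ± 71.9 in cartilage after DPBS (log2 change over all groups -4.23 ± 0.23). Also higher there were the lipid droplet gene Plin1 (-5.83), the triglyceride synthesis gene Dgat2 (-5.40), the glycerol channel gene Aqp7 (-5.10), and Cidea (-5.23) and Thrsp (-5.96). Chodl (-7.82), Edn3 (-6.40), Krt18 (-6.53), Tshr (-5.05) and the macrophage elastase Mmp12 (-4.86) were lower in cartilage. Of the joint disease genes fixed in advance, Il1b (2.75), Mmp13 (3.63), Col10a1 (5.09) and Tnf (1.15) were higher in cartilage. Adamts4 (-1.28) and Mmp3 (-0.70) were lower, and all 6 had adjusted p of 0.0282 or less.

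By list, cartilage matrix (mean log2 change 5.60), hypertrophy and mineralization (3.20), neutrophil and erythroid marrow (4.58) and cell cycle genes (3.13) rose in cartilage, and adipocyte (-3.66) and mural cell genes (-1.82) fell. Camera in limma gave Benjamini-Hochberg adjusted p of 4.3e-05 to 0.0157, and of 0.141 to 0.391 with an estimated correlation. In these 6 lists every measured member passed both over all genes tested and adjusted over the list alone. Of the 9 adipocyte genes 1 was higher in cartilage, and all other members went in the list's direction. Marrow transcripts were abundant in every cartilage library, with Mpo, the myeloperoxidase of neutrophil precursors, at 384 to 1395 CPM against 0.712 to 186 in the fat pad. Muscle transcripts varied between libraries. The myosin gene Myh2 stood at 1389 CPM in the cartilage SVF female and at 390.4 in cartilage DPBS male replicate 4, against 3.71 to 133 in the other 10 cartilage libraries. In total 13105 of 17618 genes passed an adjusted p of 0.05 in edgeR, 6812 higher and 6293 lower in cartilage. With muscle and marrow scores as covariates 5057 passed, and Edar (-0.89), Tubb1 (-0.25), Mmp13 (-0.38) and Adamts4 (0.27) turned in direction. Under them the hypertrophy and mineralization list lost its call (1.47), and the cell cycle list kept it at 1.11.

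**Figure D1:**
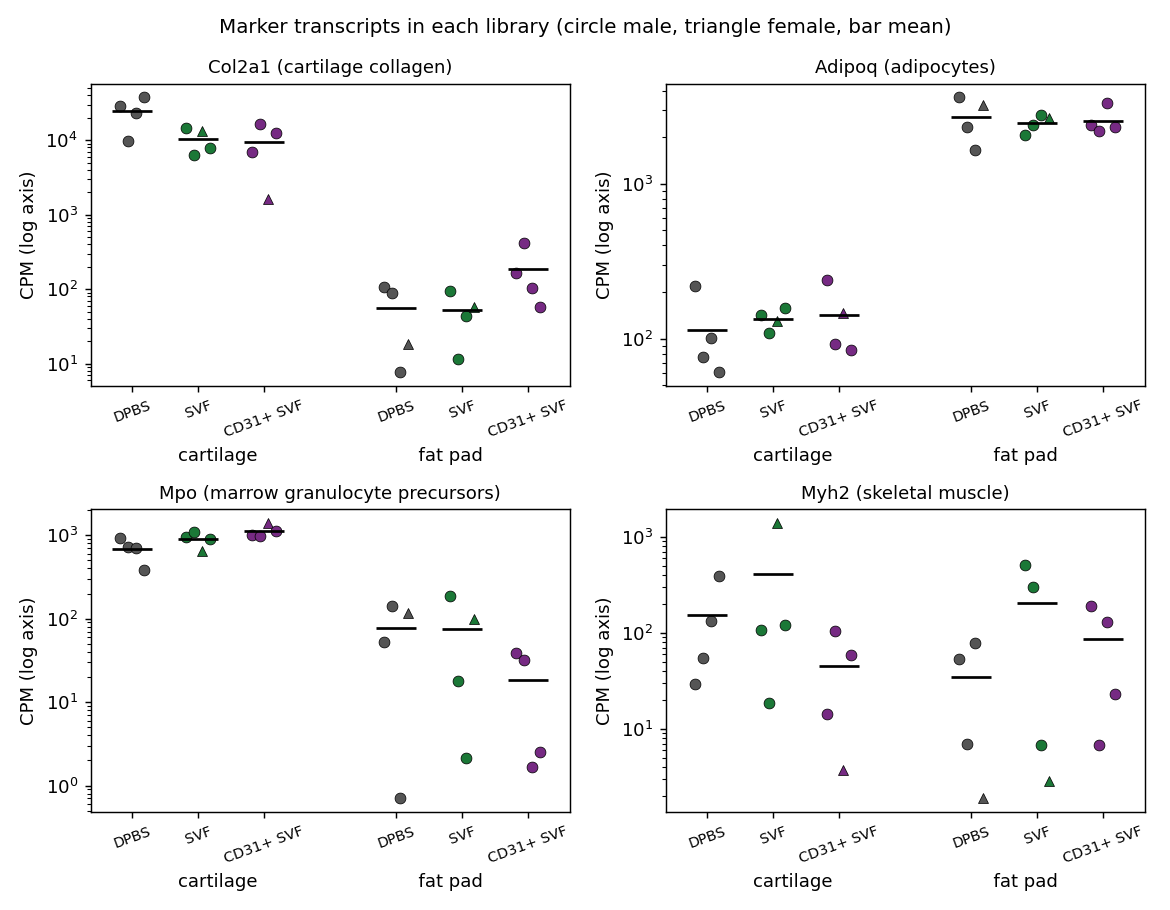
CPM on a log axis of the cartilage matrix gene Col2a1, the adipocyte gene Adipoq, the neutrophil precursor gene Mpo and the muscle gene Myh2. Each of the 12 cartilage and 12 fat pad libraries is shown by injection, with bars at the group means. Col2a1 and Mpo were higher in cartilage and Adipoq in the fat pad, while Myh2 ranged from 3.71 to 1389 CPM in cartilage and from 1.91 to 511 CPM in the fat pad.

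In cartilage after SVF, genes of matrix-degrading proteases fell as a group against DPBS. Of 11 measured members 10 were lower, with a mean log2 change of -0.97 (camera in limma, Benjamini-Hochberg adjusted p = 1.8e-08). With an estimated correlation the adjusted p was 0.280. The aggrecanase gene Adamts4 stood at 4.51 ± 1.799 against 22.4 ± 12.6 CPM (log2 change -2.08 ± 0.36). Mmp13, the collagenase of type II collagen, stood at 114 ± 22.9 against 335 ± 153 (-1.46 ± 0.32). The procollagen peptidase gene Adamts2 stood at 177 ± 40.4 against 462 ± 86.0, Adamts12 at 7.91 ± 0.839 against 16.7 ± 4.73 and Mmp11 at 4.88 ± 0.848 against 12.3 ± 5.50. With p-values adjusted over the list alone 8 of the 11 members passed, against 0 over all genes tested. Mmp3, which did not pass either way, stood at 14.6 ± 1.81 against 35.7 ± 34.5 CPM. In each of the 8 refits without 1 library the list kept its call.

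The fibroblast matrix list (mean log2 change -0.80, camera in limma, Benjamini-Hochberg adjusted p = 0.00215), the bone and osteoclast list (-0.98, adjusted p = 0.00237) and the angiogenic factor list (-0.43, adjusted p = 0.00128) also fell. With an estimated correlation their adjusted p was 0.280 to 0.511. The fibroblast list included the fibrillar and associated collagens Col5a2 (925 ± 132 against 2502 ± 733 CPM) and Col12a1 (243 ± 43.2 against 654 ± 242) and the matrix protein tenascin C (Tnc, 1069.6 ± 199 against 2913 ± 1036). Bone genes were the osteoclast protease cathepsin K (Ctsk, 437 ± 102 against 1229 ± 438) and the proton pump subunit Atp6v0d2 (13.5 ± 1.70 against 40.2 ± 16.5), among others. Angiogenic growth factor and receptor genes were Pdgfb (23.2 ± 2.77 against 32.96 ± 1.65), Nrp2 (121 ± 3.24 against 241 ± 65.8), Flt1 (79.3 ± 9.20 against 118 ± 12.9) and Igf1 (44.05 ± 7.56 against 85.2 ± 26.8). Adjusted over the list alone, 3 of 6 fibroblast, 2 of 3 bone and 4 of 9 angiogenic genes passed, and 0 over all genes tested. Another 6 lists passed with smaller margins. Hypertrophy and mineralization (-0.26), endothelial (-0.20) and TGF-beta and BMP genes (-0.12) fell, and marrow (0.54), ribosomal (0.11) and cell cycle genes (0.39) rose. Of 8 refits without 1 library, hypertrophy genes kept their call in 4 (-0.39 to -0.11), endothelial genes in 3 (-0.29 to -0.13) and TGF-beta and BMP genes in 3 (-0.27 to -0.02). Marrow genes kept it in 6 (0.33 to 0.71) and cell cycle genes in 5 (0.19 to 0.58). Under other settings the endothelial call held in 1 of 6, the TGF-beta and BMP call in 2, the cell cycle call in 2, the hypertrophy call in 3 and the ribosomal call in 4, and the marrow call in 3 of 5. Among members of these 6 lists were Panx3 at 4.49 ± 0.672 against 10.5 ± 1.82 CPM and Phex at 15.1 ± 3.40 against 28.5 ± 3.89. Eng stood at 119 ± 15.7 against 166 ± 19.9, Robo4 at 16.9 ± 2.13 against 22.0 ± 2.39 and Tie1 at 42.8 ± 8.39 against 59.7 ± 8.20. Ltbp1 stood at 264 ± 41.6 against 417 ± 96.2 and Smad3 at 29.7 ± 3.62 against 35.4 ± 4.38. Of the marrow genes Ncf4 stood at 82.5 ± 20.2 against 62.7 ± 6.71 and Csf3r at 176 ± 54.6 against 125 ± 38.2. Rps4x stood at 312 ± 11.8 against 276 ± 15.6, Tyms at 76.9 ± 24.6 against 56.9 ± 15.1 and Ube2c at 64.9 ± 20.5 against 48.4 ± 12.9. The adjusted p of these 6 lists was 0.0126 to 0.0404 in camera (limma) and 0.511 to 0.626 with an estimated correlation. Of their members 2 hypertrophy, 3 endothelial and 0 of the other 4 lists passed when adjusted over the list alone. The other 13 lists had adjusted p of 0.0904 to 0.953. Cartilage matrix (-0.14) was among them, with Col2a1 at 10545 ± 4138 against 24833 ± 11676 CPM and Acan at 2726 ± 1315 against 2794 ± 819.8.

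For single genes, 0 of 17491 passed an adjusted p of 0.05 in edgeR after SVF, with 141 under 0.1, of which 139 were lower. At an unadjusted p under 0.05 there were 2144 genes (671 higher, 1473 lower) where 875 would arise without any change. DESeq2 called 715 and voom with quality weights 1050. The lowest p among named lower genes belonged to Igsf3 (30.8 ± 4.28 against 50.04 ± 3.41 CPM, log2 change -0.75 ± 0.09, edgeR adjusted p = 0.0551) and the chloride channel gene Ano1 (23.3 ± 3.54 against 43.3 ± 3.97). Next came the laminin chain Lamb1 (48.6 ± 7.31 against 102 ± 13.7), the transcription factor gene Creb3l1 (26.8 ± 2.44 against 67.6 ± 14.7) and the sphingomyelin synthase gene Sgms2 (125 ± 13.3 against 232 ± 18.1). Among named higher genes it belonged to Rap1gap (3.76 ± 0.757 against 2.33 ± 0.223), Stx3 (62.4 ± 4.23 against 44.5 ± 6.50) and Glis1 (5.70 ± 2.95 against 1.92 ± 0.511). Arhgef1 (209 ± 16.9 against 161 ± 12.5) and Lsm10 (log2 change 0.40 ± 0.10) followed, and these 5 had edgeR adjusted p of 0.123 to 0.152. Il1b (18.2 ± 4.54 against 12.9 ± 2.53 CPM), Tnf (1.94 ± 0.538 against 1.46 ± 0.416), Col10a1 (57.5 ± 71.8 against 15.1 ± 5.18) and Adipoq (135 ± 20.1 against 114 ± 71.9) did not pass. Beside these groups, the mean log2 CPM of the marrow list was 7.30 ± 0.53 after SVF and 6.85 ± 0.44 after DPBS. That of the muscle list was 5.69 ± 2.21 and 5.11 ± 0.93. Without the SVF female, edgeR called 302 genes. It called 120 with no sex term, 341 in males alone and 250 without the 3 cartilage libraries that stood apart. Of the 10 lists 4 passed without SVF male replicate 3 and 6 without DPBS male replicate 4. With muscle and marrow scores as covariates 4 of the 9 lists other than marrow passed, and the protease list stood at -0.55.

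**Figure D2:**
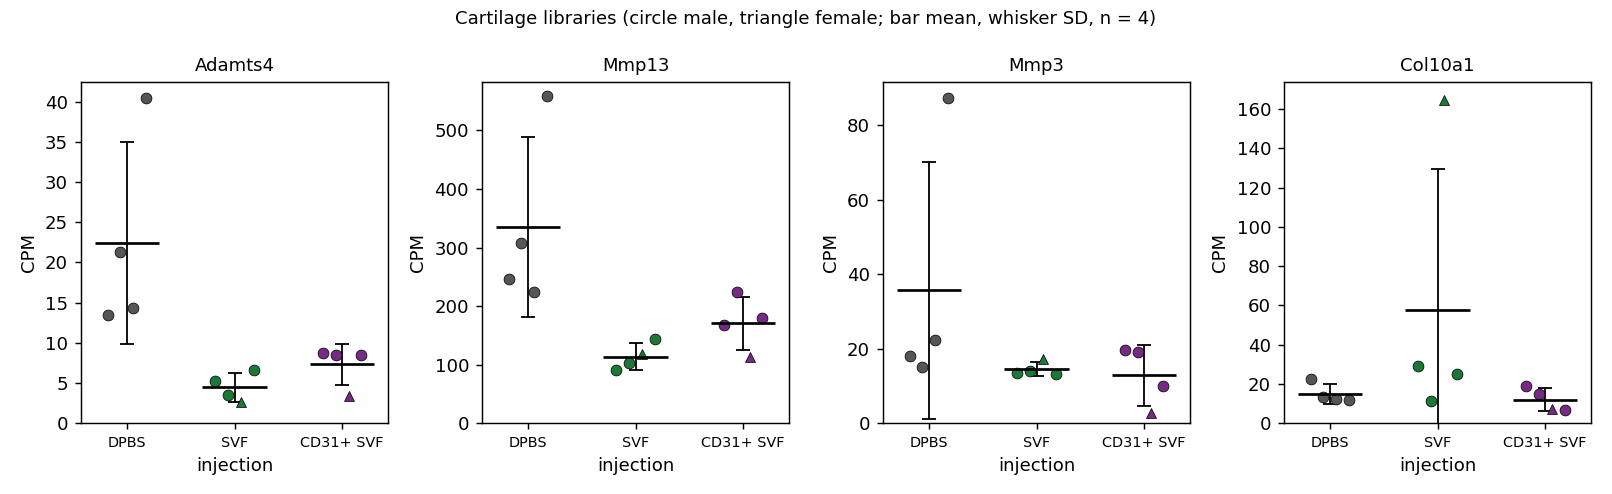
CPM of Adamts4, Mmp13, Mmp3 and Col10a1 in each cartilage library by injection, with bars at the group means ± SD. Adamts4 and Mmp13 were lower in all 4 SVF libraries than in any DPBS library, whereas Mmp3 and Col10a1 overlapped between groups.

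After CD31, cartilage showed lower values in several of the same groups against DPBS. Hypertrophy and mineralization genes (9 of 9 lower, mean log2 change -0.71) and matrix-degrading proteases (10 of 11 lower, -0.72) fell. Each had a camera adjusted p of 0.000416 (limma, Benjamini-Hochberg), and of 0.408 with an estimated correlation. Ibsp, the bone sialoprotein, stood at 472 ± 141 against 1041 ± 254 CPM, and Panx3 at 5.19 ± 1.01 against 10.5 ± 1.82. Phex stood at 17.4 ± 2.54 against 28.5 ± 3.89 and the osteocyte gene Dmp1 at 172 ± 29.8 against 291 ± 56.3. Among proteases Adamts2 stood at 225 ± 79.8 against 462 ± 86.0, and Adamts4 at 7.33 ± 2.59 against 22.4 ± 12.6. Adamts12 stood at 8.73 ± 1.95 against 16.7 ± 4.73 and the membrane-bound Mmp14 at 269 ± 98.0 against 582 ± 190.4. Of these lists 4 hypertrophy and 7 protease genes passed adjusted over the list alone, and 0 over all genes tested. Fibroblast matrix (-0.97), bone and osteoclast (-0.79), angiogenic (-0.37), TGF-beta and BMP (-0.47), Wnt (-0.64), cartilage matrix (-0.87) and muscle genes (-1.99) fell too. Marrow (0.80) and cell cycle genes (0.65) rose. Their camera adjusted p (limma) was 0.000416 to 0.0483, and 0.408 to 0.529 with an estimated correlation.

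Fibroblast and bone genes in these lists included Col12a1 (247 ± 87.9 against 654 ± 242 CPM), Col5a2 (1095 ± 597 against 2502 ± 733), Ctsk (533 ± 180.2 against 1229 ± 438) and Atp6v0d2 (20.1 ± 6.08 against 40.2 ± 16.5). Signalling genes included Nrp2 (131 ± 19.0 against 241 ± 65.8), Pdgfb (25.0 ± 1.06 against 32.96 ± 1.65), the inhibitory Smad gene Smad6 (8.80 ± 1.12 against 15.7 ± 2.12) and Smad3 (28.4 ± 1.64 against 35.4 ± 4.38). Wnt genes were the beta-catenin gene Ctnnb1 (551 ± 79.5 against 788 ± 76.3), Ccn4 (19.9 ± 7.88 against 60.3 ± 25.2) and the Wnt co-receptor gene Lrp5 (76.9 ± 15.4 against 112 ± 13.0). Hgf, an angiogenic gene, went the other way from its list (47.0 ± 7.10 against 26.5 ± 7.33). Marrow genes stood at 1132 ± 188 against 683 ± 222 CPM for Mpo, 97.4 ± 9.74 against 62.7 ± 6.71 for Ncf4 and 218 ± 26.7 against 125 ± 38.2 for Csf3r. Cell cycle genes stood at 38.9 ± 6.48 against 26.3 ± 5.94 for Cdk1 and 87.4 ± 15.3 against 56.9 ± 15.1 for Tyms. Col2a1 stood at 9391 ± 6561 against 24833 ± 11676, Acan at 1723 ± 875 against 2794 ± 819.8 and Col9a3 at 95.9 ± 60.6 against 231 ± 91.3. The muscle gene Myh2 stood at 45.1 ± 45.8 against 152 ± 165 and Tcap at 14.2 ± 10.2 against 32.6 ± 26.1. When adjusted over the list alone, members passed in the Wnt (6 of 10), angiogenic (6 of 9), TGF-beta and BMP (5 of 11), marrow (4 of 5), fibroblast (3 of 6) and bone lists (3 of 3). In the cartilage matrix, muscle and cell cycle lists 0 passed. Without 1 library the muscle list kept its call in 4 of 8 refits (-3.38 to -0.80) and the cartilage matrix list in 3 (-1.17 to -0.56). The other 12 lists had adjusted p of 0.0828 to 0.700.

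For single genes, edgeR called 0 of 17491 after CD31 (lowest adjusted p 0.106). There were 4144 at an unadjusted p under 0.05 (1733 higher, 2411 lower), and DESeq2 called 1401 and voom with quality weights 1770. The named lower genes with the lowest p were Igsf3 (30.1 ± 1.64 against 50.04 ± 3.41 CPM, log2 change -0.77 ± 0.09), the netrin receptor gene Unc5b (89.6 ± 11.2 against 155 ± 12.7). Next came the kinase gene Nuak1 (14.2 ± 2.62 against 26.7 ± 3.78), Scarf2 (35.5 ± 7.37 against 66.8 ± 5.73) and the guidance factor gene Slit3 (82.6 ± 3.62 against 116 ± 7.60). The named higher genes were Nt5c2 (80.9 ± 3.03 against 60.6 ± 5.76), Stx3 (64.04 ± 5.06 against 44.5 ± 6.50) and Mindy1 (96.1 ± 8.48 against 72.2 ± 5.98). B3gnt5 (53.4 ± 2.84 against 35.7 ± 6.52) and Ampd2 (113 ± 11.2 against 83.2 ± 6.61) followed, and all 5 had edgeR adjusted p of 0.132 to 0.143. Mmp13 (171 ± 45.3 against 335 ± 153 CPM), Mmp3 (12.9 ± 8.09 against 35.7 ± 34.5) and Il1b (20.6 ± 3.82 against 12.9 ± 2.53) did not pass. Nor did Tnf (2.48 ± 0.878 against 1.46 ± 0.416), Col10a1 (12.1 ± 5.95 against 15.1 ± 5.18) and Adipoq (141 ± 71.7 against 114 ± 71.9). The marrow score was 7.57 ± 0.25 log2 CPM after CD31 and 6.85 ± 0.44 after DPBS. With muscle and marrow scores as covariates 1 of the 9 lists other than muscle and marrow passed. The protease list then stood at -0.26, the hypertrophy list at -0.30, the cartilage matrix list at 0.04 and the cell cycle list at -0.11. Without the 3 cartilage libraries that stood apart the muscle (-0.38), cartilage matrix (-0.39) and angiogenic calls (-0.21) ended, and the cell cycle list moved to 0.25. EdgeR called 1 gene without CD31 male replicate 2, 1 without the CD31 female and 1 in males alone.

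CD31 was also compared with SVF in cartilage, which addresses what the enrichment added. Muscle genes fell (9 of 9 lower, mean log2 change -2.38), with Tcap at 14.2 ± 10.2 against 67.6 ± 88.7 CPM and Tnni2 at 39.5 ± 30.2 against 164 ± 216. Cartilage matrix (-0.73), hypertrophy and mineralization (-0.46), protease inhibitors (-0.79), TGF-beta and BMP (-0.35) and Wnt genes (-0.36) fell, and matrix-degrading proteases (0.25), macrophage (0.24), lymphocyte (0.50) and cell cycle genes (0.27) rose. In refits without 1 library these values ranged from -3.54 to -0.41 for muscle, -0.99 to -0.07 for cartilage matrix, -0.60 to -0.14 for hypertrophy and -1.03 to -0.40 for protease inhibitors. The ranges were -0.45 to -0.05 for TGF-beta and BMP, -0.48 to -0.02 for Wnt, 0.05 to 0.33 for macrophage, 0.04 to 0.67 for lymphocyte and -0.13 to 0.45 for cell cycle genes. The 10 lists had Benjamini-Hochberg adjusted p of 0.000384 to 0.0385 in camera (limma), and 0.598 to 0.652 with an estimated correlation. Comp, a cartilage matrix protein, stood at 3983 ± 940.1 against 6938 ± 3589.9, and Snorc at 52.6 ± 20.4 against 118 ± 86.1. Ankh stood at 339 ± 61.1 against 485 ± 106 and Col10a1, the collagen of hypertrophic chondrocytes, at 12.1 ± 5.95 against 57.5 ± 71.8. Serpine2 stood at 773 ± 251 against 1222 ± 514, Bmp5 at 10.5 ± 1.20 against 17.7 ± 9.70 and Smad6 at 8.80 ± 1.12 against 12.7 ± 3.17. The secreted Wnt antagonist Frzb stood at 167 ± 93.7 against 490.4 ± 394 and Lrp5 at 76.9 ± 15.4 against 99.6 ± 25.3. Adamts4 stood at 7.33 ± 2.59 against 4.51 ± 1.799, Mmp13 at 171 ± 45.3 against 114 ± 22.9 and Adamts9 at 34.8 ± 3.31 against 28.3 ± 2.92. The macrophage gene Mrc1 stood at 75.9 ± 4.03 against 65.2 ± 12.8 and Cd86 at 13.0 ± 0.308 against 10.5 ± 3.16. The lymphocyte gene Il7r stood at 8.31 ± 1.45 against 4.98 ± 1.74 and Cd4 at 5.35 ± 6.64 against 1.51 ± 0.264. The cell cycle gene Bub1b stood at 110.3 ± 20.5 against 86.8 ± 28.9 and Cdk1 at 38.9 ± 6.48 against 32.4 ± 10.02. Of the 3 protease inhibitors 1 passed adjusted over the list alone (Timp4, 6.41 ± 1.21 against 15.2 ± 9.47), and 0 members of the other 9 lists, and 0 over all genes tested.

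EdgeR called 0 of 17491 genes between CD31 and SVF cartilage (lowest adjusted p 0.822). There were 847 at an unadjusted p under 0.05 where 875 would arise without any change, and DESeq2 called 14 and voom 0. Without CD31 male replicate 2 edgeR called 1. The named higher genes with the lowest p were Steap4 (78.1 ± 10.04 against 60.3 ± 10.2 CPM), Egln3 (18.9 ± 3.56 against 13.6 ± 0.684) and St8sia4 (66.5 ± 6.14 against 50.2 ± 10.4). Dock4 (15.1 ± 1.27 against 11.9 ± 0.802) and Slc39a10 (35.9 ± 1.66 against 30.8 ± 2.26) followed. On the lower side they were the chemokine gene Cx3cl1 (14.6 ± 1.96 against 21.7 ± 3.59), Spag6 (2.04 ± 0.474 against 3.91 ± 0.708), Cmbl (10.03 ± 0.629 against 13.1 ± 1.78) and Cytl1 (476 ± 207 against 1333 ± 1132), besides Timp4. Col2a1 (9391 ± 6561 against 10545 ± 4138), Acan (1723 ± 875 against 2726 ± 1315) and Mmp3 (12.9 ± 8.09 against 14.6 ± 1.81) did not pass. Values for the others were Il1b (20.6 ± 3.82 against 18.2 ± 4.54), Tnf (2.48 ± 0.878 against 1.94 ± 0.538) and Adipoq (141 ± 71.7 against 135 ± 20.1). Of the lists, 0 passed in males alone or (the same contrast) without either female. Without the 3 cartilage libraries that stood apart, only matrix-degrading proteases (0.26) and protease inhibitors (-0.40) of the 10 kept their call. With muscle and marrow scores as covariates only matrix-degrading proteases did. In males the cell cycle list turned to -0.13 and Col2a1 to 0.32. Myh2, at 1389 CPM in the SVF female, stood at 3.71 in the CD31 female, the highest and the lowest of the 12 cartilage libraries.

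In cartilage, the log2 changes after SVF and after CD31 were correlated across genes, with both measured against the same DPBS libraries. Pearson's r across 17491 genes was 0.670. Unchanged simulated groups sharing the reference gave a mean of 0.545 and at most 0.562, and genes are not independent replicates. The simulation drew each gene independently, without variation that the genes of a library share. It therefore cannot show likeness beyond the shared reference. With the DPBS libraries split so that each comparison had its own 2, r averaged 0.352 over 6 splits (0.153 to 0.474). The covariance of the changes was 0.154 against 0.0701 simulated, a difference of 0.0836. Of genes lower at an unadjusted edgeR p under 0.05, 1473 after SVF and 2411 after CD31, 1101 were shared. Independent sets of these sizes would share 203, and unchanged simulated groups sharing the reference shared 92.5 of 427 and 408 on average. Of the 671 and 1733 higher genes 336 were shared, against 66.5 for independent sets and 113 of 416 and 408 in the simulated groups. In the fat pad, r was 0.328 against a simulated mean of 0.486. It was -0.141 on average with split DPBS libraries (-0.360 to 0.169), so r gave no likeness beyond the shared reference there. The covariance was 0.0477 against 0.0642 simulated.

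**Figure D3:**
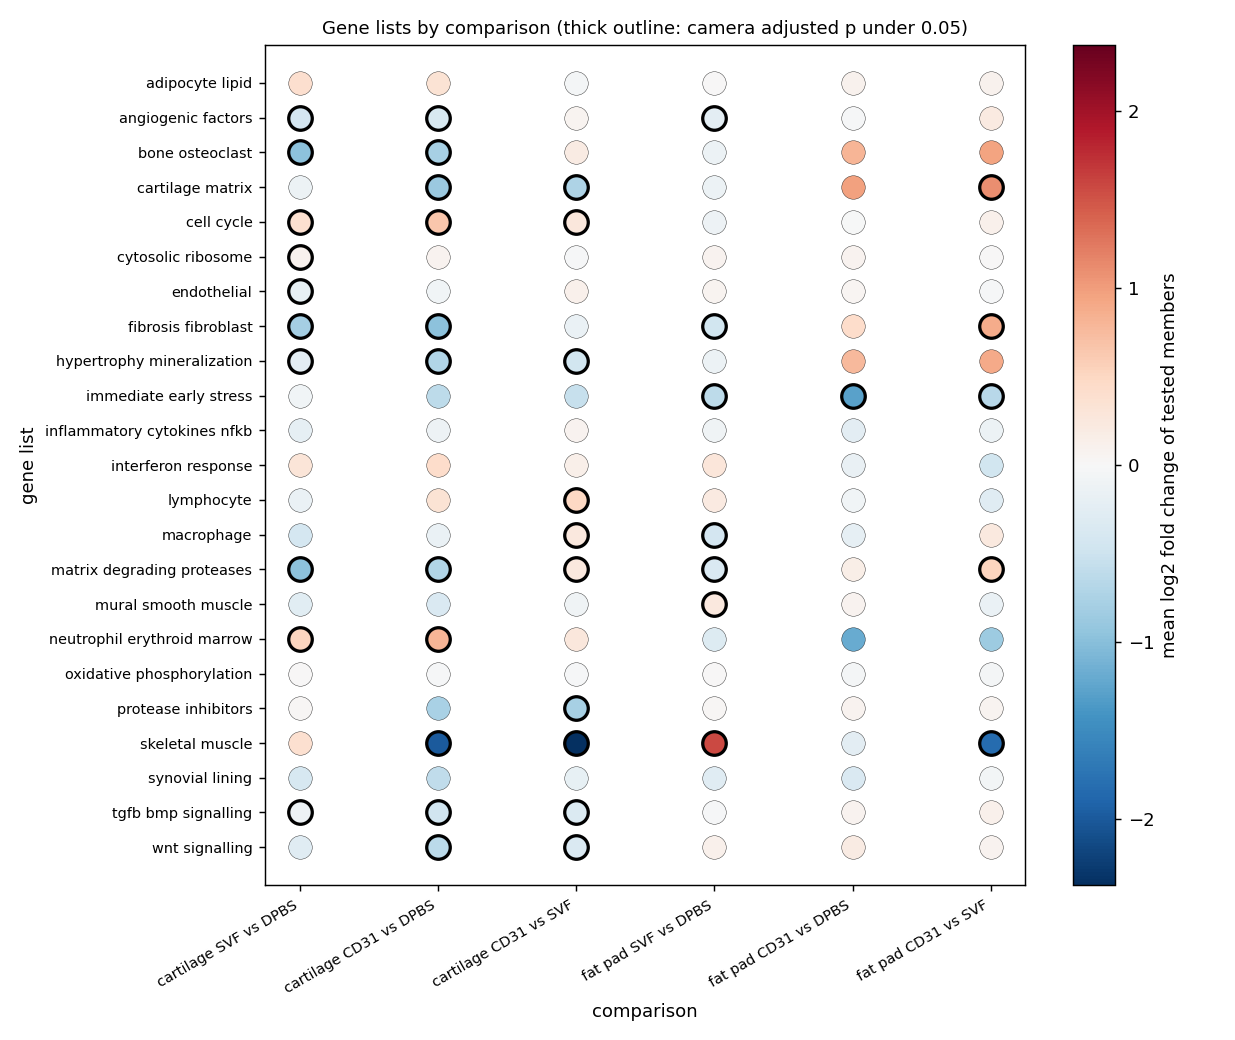
Mean log2 change of each tested gene list (vertical axis) in each treatment comparison (horizontal axis). Color gives the size and direction of the change, with a thick outline where camera gave an adjusted p under 0.05. The outlined lists fall mostly in the cartilage comparisons, whereas the fat pad CD31 against DPBS column has 1, the immediate early genes.

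In the fat pad after SVF, 7 lists passed against DPBS. Matrix-degrading proteases (8 of 11 lower, mean log2 change -0.37), immediate early (-0.63), fibroblast matrix (-0.45), macrophage (-0.44) and angiogenic genes (-0.25) fell. Mural cell (0.25) and muscle genes (1.57) rose. With any 1 library left out, immediate early genes ranged from -1.14 to -0.32, fibroblast genes from -0.65 to -0.15, macrophage genes from -0.56 to -0.26, proteases from -0.49 to -0.20 and muscle genes from 0.86 to 2.89. Of 8 such refits muscle and macrophage genes kept their call in 2 each, fibroblast and mural genes in 3 each, angiogenic genes in 4 and immediate early genes in 5. Without library numbers above 50 the protease (-0.21), mural (0.05), macrophage and angiogenic calls ended. With muscle and marrow scores as covariates proteases and mural genes alone kept theirs. The adjusted p of these 7 lists was 0.00664 to 0.0352 (camera in limma, Benjamini-Hochberg), and 0.347 to 0.707 with an estimated correlation. Mmp3 stood at 23.6 ± 8.11 against 48.7 ± 15.5 CPM (log2 change -1.01 ± 0.18). Adamts9 stood at 70.2 ± 14.3 against 139.5 ± 54.2 and Adamts4 at 12.2 ± 4.07 against 39.1 ± 39.6, while Mmp12 went the other way (27.0 ± 16.3 against 13.6 ± 11.8). Adjusted over the list alone, 5 protease and 2 mural genes passed, 0 members of the other 5 lists, and 0 of all 7 lists over all genes tested. The mural genes were the smooth muscle genes Myl9 (409 ± 71.9 against 299.9 ± 40.2) and Myh11 (1719 ± 356 against 1284 ± 222). Further members were Myc (50.95 ± 2.91 against 84.1 ± 40.1), Btg2 (129 ± 32.4 against 366 ± 347), Col5a2 (1084 ± 335 against 1674 ± 874) and Bgn (2351 ± 613 against 3387 ± 1615). The macrophage genes Laptm5 (159.7 ± 18.9 against 185 ± 17.6) and Cd86 (8.75 ± 0.841 against 11.2 ± 2.59) were lower. So were Thbs2 (528 ± 107 against 802 ± 331) and Adm (57.6 ± 19.1 against 86.2 ± 35.2), members of the angiogenic factor list. Muscle genes included Mybpc1 (186 ± 203 against 45.8 ± 45.8) and Mybpc2 (82.4 ± 108.4 against 5.997 ± 8.66). The other 16 lists had adjusted p of 0.0958 to 0.990.

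EdgeR called 1 of 16907 genes after SVF in the fat pad, ENSCPOG00000031544, a gene without a symbol that was named after its values were seen. It fell (13.4 ± 2.77 against 24.1 ± 2.86 CPM, log2 change -0.86 ± 0.09, adjusted p = 0.0265). At an unadjusted p under 0.05 there were 1495 genes, and DESeq2 called 63 and voom 1. The named higher genes with the lowest p, which did not pass, were Akap6 (9.87 ± 2.01 against 6.02 ± 1.13 CPM), the synaptotagmin gene Syt1 (9.66 ± 1.36 against 3.799 ± 1.25) and Rcan2 (41.3 ± 6.42 against 27.1 ± 4.37). Cldn11 (28.4 ± 2.74 against 21.8 ± 1.85) and Cap2 (26.9 ± 5.69 against 17.9 ± 2.98) followed. On the lower side, besides Mmp3 and Adamts9, they were the collagens Col14a1 (2286 ± 253 against 3498 ± 701) and Col28a1 (49.8 ± 11.2 against 116 ± 32.8) and Rgs3 (126 ± 6.52 against 159.9 ± 8.14). Adipoq (2475 ± 312 against 2710.3 ± 892), Il1b (2.75 ± 1.30 against 4.46 ± 1.09), Tnf (0.996 ± 0.253 against 0.885 ± 0.424) and Mmp13 (12.02 ± 12.2 against 8.57 ± 3.62) did not pass. The same held for Col2a1 (52.3 ± 34.4 against 55.4 ± 49.7), Acan (54.8 ± 52.98 against 107 ± 136) and Col10a1 (0.111 ± 0.0834 against 1.52 ± 2.93). The muscle score ranged widely, 5.27 ± 2.73 log2 CPM after SVF and 3.76 ± 1.94 after DPBS. Myh2 stood at 1.91 to 511 CPM over the 12 fat pad libraries. EdgeR called 0 genes without DPBS male replicate 1, the DPBS female or any 1 of the 4 SVF libraries, and 3 without DPBS male replicate 2. In the fit by sex and replicate number it called 0. Of the 7 lists 1 passed without DPBS male replicate 2, 3 without SVF male replicate 2, and 2 in males alone or without either female.

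After CD31, immediate early genes, the transcripts induced fast by growth factors and tissue handling alike, fell in the fat pad against DPBS. Of 10 measured members 9 were lower, with a mean log2 change of -1.28 (camera in limma, Benjamini-Hochberg adjusted p = 1.2e-06). The adjusted p with an estimated correlation was 0.576. Klf6 stood at 307 ± 39.2 against 499.8 ± 87.6 CPM (log2 change -0.73 ± 0.14) and Myc at 40.0 ± 2.13 against 84.1 ± 40.1. Atf3 stood at 24.1 ± 14.2 against 118 ± 109 and Btg2 at 87.2 ± 50.5 against 366 ± 347. Of the list, 6 members passed adjusted over it alone, and 0 over all genes tested. The other 22 lists had adjusted p of 0.143 to 0.973. Among them were cartilage matrix (0.97), matrix-degrading proteases (0.15) and inflammatory genes (-0.25). EdgeR called 4 of 16907 genes. Nrep, a neuronal regeneration-related gene, rose to 159 ± 31.8 against 71.1 ± 12.8 CPM (log2 change 1.07 ± 0.14, adjusted p = 0.0433), higher in all 4 CD31 libraries than in any DPBS library. The other 3 have no symbol and were named after their values were seen. ENSCPOG00000019616 (12.1 ± 1.75 against 5.05 ± 3.20 CPM, adjusted p = 0.0201) and ENSCPOG00000036930 (20.03 ± 1.65 against 8.05 ± 3.96, adjusted p = 0.0433) rose, and ENSCPOG00000031177 fell (10.9 ± 0.493 against 20.9 ± 4.39, adjusted p = 0.0115; edgeR).

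At an unadjusted p under 0.05 there were 1600 genes in this comparison, and DESeq2 called 204 and voom 5. Named higher genes with the lowest p that did not pass were the clock gene Nr1d2 (270.5 ± 22.4 against 174 ± 27.8 CPM) and the cortisol-inactivating enzyme gene Hsd11b2 (10.7 ± 4.99 against 3.49 ± 1.35). Dnaaf3 (3.90 ± 0.391 against 2.32 ± 0.396) and Trmu (18.04 ± 0.229 against 14.5 ± 0.790) followed. On the lower side, beside Klf6, they were the glucocorticoid-induced kinase gene Sgk1 (113 ± 9.32 against 203 ± 56.9) and Csrnp1 (23.1 ± 4.75 against 59.2 ± 21.6). Rgs3 (121 ± 9.28 against 159.9 ± 8.14) and the hepatocyte growth factor receptor gene Met (74.9 ± 10.3 against 122 ± 14.6) came next. Il1b stood at 1.58 ± 0.472 against 4.46 ± 1.09 CPM, Mmp3 at 31.0 ± 6.98 against 48.7 ± 15.5 and Mmp13 at 43.3 ± 41.5 against 8.57 ± 3.62. Adamts4 stood at 26.6 ± 9.37 against 39.1 ± 39.6, Col2a1 at 186 ± 159.5 against 55.4 ± 49.7, and Acan at 211 ± 107 against 107 ± 136. Col10a1 stood at 1.61 ± 1.82 against 1.52 ± 2.93, Tnf at 0.893 ± 0.224 against 0.885 ± 0.424 and Adipoq at 2558 ± 503 against 2710.3 ± 892. None of these 9 passed in edgeR. Beside them, the marrow score was 1.88 ± 1.51 log2 CPM after CD31 and 3.37 ± 1.60 after DPBS. Without 1 library, edgeR called 0 genes (CD31 male replicate 1 or 2), 1 (DPBS male replicate 2), 2 (DPBS male replicate 1, or CD31 male replicate 4) and 11 (DPBS male replicate 3). It called 0 with no sex term and 0 in the fit by sex and replicate number. The lists past the threshold numbered 5 without DPBS male replicate 3, 4 without DPBS male replicate 1 and 2 without CD31 male replicate 2 or 4. The call of Nrep was lost in 6 of the 8 refits without 1 library, with log2 changes of 0.94 to 1.17 and adjusted p of 0.0350 to 0.236. It held without DPBS male replicate 3 or CD31 male replicate 4.

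**Figure D4:**
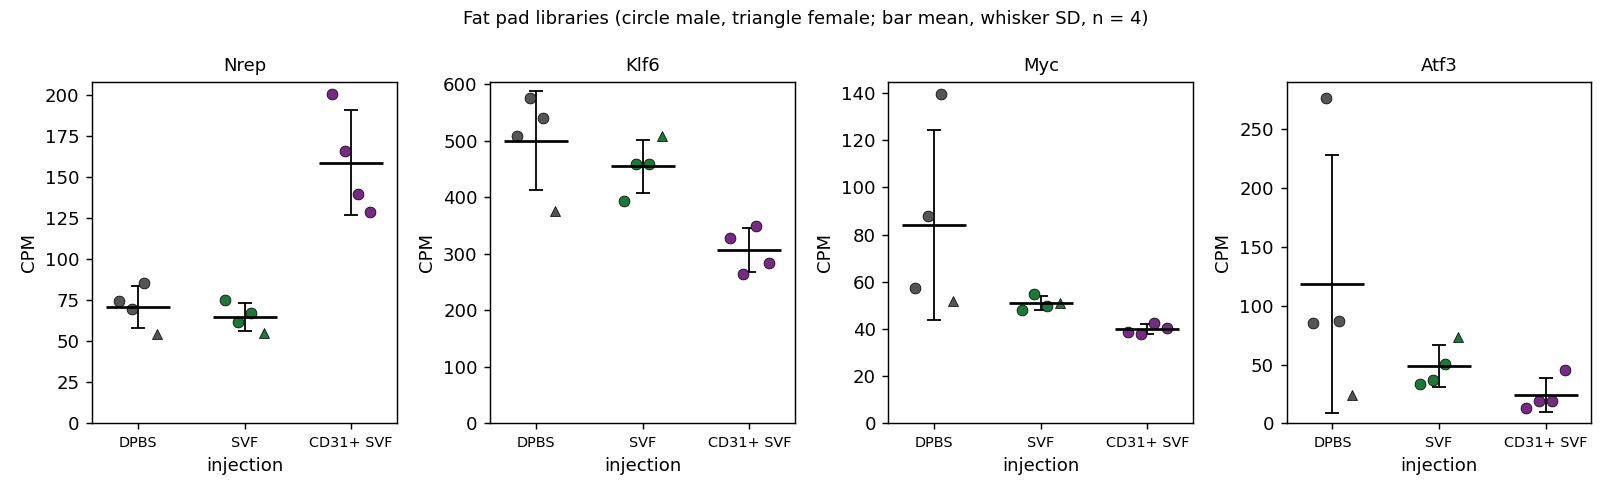
CPM of Nrep, Klf6, Myc and Atf3 in each fat pad library by injection, with bars at the group means ± SD. Nrep was higher in all 4 CD31 libraries than in any DPBS or SVF library, and Klf6 and Myc were lower in all 4 CD31 libraries than in any other.

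Against SVF in the fat pad, CD31 libraries had higher fibroblast matrix (6 of 6 higher, mean log2 change 0.89), matrix-degrading protease (9 of 11, 0.52) and cartilage matrix genes (6 of 6, 1.11). They had lower immediate early (-0.65) and muscle genes (-1.82). With 1 library left out, proteases ranged from 0.30 to 0.69, immediate early genes from -0.86 to -0.39 and muscle genes from -3.19 to -1.07, the last with its call kept in 5 of 8 refits. The immediate early call ended without SVF male replicate 3, with no sex term (-0.54), in males alone (-0.40) and without library numbers above 50 (-0.20). Muscle genes lost theirs with no sex term (-0.94) and proteases without library numbers above 50 (0.33). These 5 lists had camera adjusted p of 0.000616 to 0.0136 (limma, Benjamini-Hochberg), and adjusted p of 0.4004 to 0.635 with an estimated correlation. Col5a2 stood at 2817 ± 747 against 1084 ± 335 CPM, Bgn at 4717 ± 790.3 against 2351 ± 613 and Col12a1 at 789 ± 537 against 249 ± 86.0. Adamts2 stood at 511 ± 145 against 222 ± 47.6 and Mmp14 at 828 ± 268 against 425 ± 64.8. Of the cartilage matrix genes, Col9a3 stood at 6.20 ± 3.55 against 2.64 ± 0.333 and Acan at 211 ± 107 against 54.8 ± 52.98. Hapln1, the link protein of aggrecan, stood at 79.3 ± 38.7 against 23.9 ± 19.9 and Col2a1 at 186 ± 159.5 against 52.3 ± 34.4. Klf6 stood at 307 ± 39.2 against 455 ± 47.2, and Myc at 40.0 ± 2.13 against 50.95 ± 2.91. Tcap stood at 21.8 ± 18.9 against 67.8 ± 63.1 and Mybpc1 at 62.3 ± 40.9 against 186 ± 203. Adjusted over the list alone 2 fibroblast, 3 protease, 1 immediate early and 0 cartilage matrix and muscle genes passed, and 0 over all genes tested. The other 18 lists had adjusted p of 0.0800 to 0.814.

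EdgeR called 0 of 16907 genes between CD31 and SVF fat pads. There were 1727 at an unadjusted p under 0.05 where 845 would arise without any change, and DESeq2 called 220 and voom 1. Nrep had the lowest p, at 159 ± 31.8 against 64.6 ± 8.47 CPM (log2 change 1.20 ± 0.14, adjusted p = 0.0602, edgeR). It was followed on the higher side by the potassium channel gene Kcnk6 (34.0 ± 2.33 against 24.5 ± 2.32) and the chloride transporter gene Clcn7 (74.2 ± 6.39 against 57.4 ± 3.97). Adamts12 (44.2 ± 10.97 against 26.8 ± 0.964) and Crtap, a collagen prolyl hydroxylation partner (152 ± 20.1 against 108.1 ± 5.39), came after them. On the lower side stood Syt1 (2.95 ± 0.851 against 9.66 ± 1.36), Hddc3 (8.88 ± 0.320 against 11.8 ± 0.487) and Myo18a (117 ± 4.85 against 152 ± 10.3). The dystrophin gene Dmd (23.0 ± 3.01 against 32.6 ± 3.12) and Akap6 (7.11 ± 0.759 against 9.87 ± 2.01) followed. Mmp13 (43.3 ± 41.5 against 12.02 ± 12.2), Mmp3 (31.0 ± 6.98 against 23.6 ± 8.11) and Adamts4 (26.6 ± 9.37 against 12.2 ± 4.07) did not pass. The values of the rest were Il1b (1.58 ± 0.472 against 2.75 ± 1.30), Tnf (0.893 ± 0.224 against 0.996 ± 0.253), Col10a1 (1.61 ± 1.82 against 0.111 ± 0.0834) and Adipoq (2558 ± 503 against 2475 ± 312). The muscle score was 4.41 ± 1.79 log2 CPM after CD31 and 5.27 ± 2.73 after SVF. The bone and osteoclast score stood at 6.56 ± 0.60 and 5.61 ± 0.45, and the marrow score at 1.88 ± 1.51 and 3.01 ± 1.86. Without CD31 male replicate 4 edgeR called 1 gene. The lists that passed numbered 3 of 5 without SVF male replicate 2 or without CD31 male replicate 2.

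Whether a preparation acted differently in the 2 tissues was tested as an interaction over all 24 libraries. For CD31, edgeR called 97 of 17618 genes (16 with a more positive change in cartilage than in the fat pad, 81 with a more negative one). Nrep, the gene that rose in the fat pad, stood in cartilage at 57.5 ± 23.6 CPM after CD31 and 104 ± 6.13 after DPBS (interaction log2 -1.92 ± 0.34, adjusted p = 0.0294). Myc stood at 75.1 ± 12.3 and 55.3 ± 3.71 in cartilage against 40.0 ± 2.13 and 84.1 ± 40.1 in the fat pad (1.64 ± 0.32, adjusted p = 0.0295, edgeR). Creb3l1 (-1.76), the corepressor gene Rcor2 (-2.21), Hsd11b2 (-2.07) and Insc (-2.69) were the other named genes with a more negative change in cartilage. The prostaglandin receptor gene Ptger2 (0.996), Nt5c2 (0.63), the platelet-activating factor receptor gene Ptafr (1.06) and Hddc3 (0.58) were those with a more positive one. At an unadjusted p under 0.05 there were 3737 genes, and DESeq2 called 1019 and voom 1807. By list, hypertrophy and mineralization (-1.51), bone and osteoclast (-1.56), fibroblast matrix (-1.39), matrix-degrading protease (-0.86) and TGF-beta and BMP genes (-0.54) changed more negatively in cartilage. Marrow (2.12), cell cycle (0.76) and immediate early genes (0.65) changed more positively. The immediate early value ranged from 0.30 to 1.02 in 16 refits without 1 library and passed in 6. The cell cycle call ended in males alone (0.42) and without the 3 cartilage libraries that stood apart (0.26), and with muscle and marrow scores as covariates the list turned to -0.38. Under the covariates TGF-beta and BMP genes lost their call as well (-0.23), and with no sex term immediate early genes (0.38). The adjusted p of these 8 lists was 0.00377 to 0.0464 (camera in limma, Benjamini-Hochberg), and 0.396 to 0.542 with an estimated correlation. Adjusted over the list alone 6 protease, 3 fibroblast, 2 bone, 1 hypertrophy, 1 TGF-beta and BMP, 1 marrow, 1 immediate early and 0 cell cycle genes passed. Over all genes tested, 1 protease and 1 immediate early gene passed.

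The count of 97 rested on single libraries. Without 1 it was 0 (fat pad DPBS male replicate 2), 3 (cartilage CD31 male replicate 1), 5 (cartilage DPBS male replicate 4, fat pad DPBS male replicate 1 or fat pad CD31 male replicate 4) or 6 (fat pad CD31 male replicate 1). It was 17 (cartilage CD31 male replicate 3), 41 (cartilage DPBS male replicate 1), 54 (the cartilage CD31 female) or 57 (cartilage DPBS male replicate 3). Further counts were 60 (the fat pad DPBS female), 639 (fat pad DPBS male replicate 3) and 994 (cartilage CD31 male replicate 2). Of the 8 lists 5 passed without fat pad CD31 male replicate 2. For SVF, edgeR called 1 gene, ENSCPOG00000006998, without a symbol and named after its values were seen. Its change was more negative in cartilage (interaction log2 -1.29 ± 0.17, adjusted p = 0.00597, edgeR). At an unadjusted p under 0.05 there were 1321 genes, with 79 called by DESeq2 and 26 by voom. Without 1 library edgeR called 3 (fat pad SVF male replicate 1) or 2 genes (cartilage DPBS male replicate 2, fat pad DPBS male replicate 1, the fat pad DPBS female or fat pad SVF male replicate 3). Mural cell (-0.52) and matrix-degrading protease genes (-0.65) changed more negatively in cartilage and immediate early genes (0.55) more positively. In 16 refits without 1 library the immediate early call held in 7 (0.23 to 0.99) and the protease call in 8. The protease call also ended in males alone (-0.50) and without the 3 cartilage libraries (-0.43), the mural call without library numbers above 50 (-0.36) and the immediate early call with no sex term (0.40). The adjusted p of the 3 lists was 0.0209 to 0.0400 (camera in limma, Benjamini-Hochberg), and 0.0967 to 0.702 with an estimated correlation. Of their members 1 mural, 2 protease and 0 immediate early genes passed adjusted over the list alone, and 0 over all genes tested. Of these 3 lists 0 passed without cartilage SVF male replicate 1 and 1 without fat pad DPBS male replicate 2. In contrast 9 lists passed without fat pad DPBS male replicate 3 and 5 without cartilage DPBS male replicate 1 or fat pad SVF male replicate 3. The labels do not say whether libraries came from separate animals, so all p-values measure the spread between these samples.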

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

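Of the tests in this part, the comparison of protease with cartilage matrix scores and both tests on liver transcripts were chosen only after the result was seen. Gene lists, comparisons and the alternatives not named as later choices were fixed before the data were examined. The lower matrix-degrading protease list of cartilage after SVF was weighed first. With the marrow score as a covariate the difference in list score between SVF and DPBS was -0.72 log2 units (95% interval -1.21 to -0.24), and without it -0.96 (-1.46 to -0.46), which argues against a larger share of marrow cells as the whole source. Without cartilage DPBS male replicate 4 the list mean stayed at -0.77 (camera adjusted p = 8.7e-11), which argues against that library as the source. Fewer cells of the skeletal compartment stay open: protease minus cartilage matrix scores differed by -0.84, exact permutation p = 0.229 over 70 relabellings, whose lowest p is 0.0286. An effect of SVF itself stays among the open explanations.

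Liver transcripts were measured in 1 cartilage library, DPBS male replicate 4. Alb, the serum albumin of hepatocytes, stood there at 773 CPM against at most 0.169 in the other 11 cartilage libraries, and Cps1, a urea cycle enzyme, at 62.1 against at most 0.113 (scaled over all genes of the 12 libraries). Of 11 liver markers whose values had not been looked at, 81.8 percent (9 of 11) were highest in that library where 8.33 percent would be by chance, and 6 of the 11 stood at over 1 CPM in another cartilage library, so RNA of liver is a candidate source of these transcripts. Col2a1 stood at 38864 CPM in that library and at 1634 to 28315 in the others, which argues against a library of another tissue. No biological explanation was tested, and how such RNA entered the library stays open.

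The lower immediate early list of the fat pad after CD31 was also weighed. Without fat pad DPBS male replicate 3 the list mean was -1.14 (camera adjusted p = 0.000670), which argues against that library as the source. With the marrow score as a covariate the difference in list score was -1.34 (95% interval -2.56 to -0.12), and without it -1.27 (-2.34 to -0.19), which argues against a share of marrow cells as the source. Time from death to freezing, which the labels do not give, and an effect of CD31 itself stay open and were not tested.

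Within groups of 4, single libraries far from the other 3 were looked for with Dixon's test, which chance alone meets in about 1 in 20 groups. Of 138 list scores 8 passed (6.90 by chance), of 330 named gene values 24 (16.5 by chance), and of 24 depth and composition measures 0 (1.20 by chance). All values are log2 CPM with the range of the other 3 libraries. The cartilage SVF female recurred, with the marrow list (6.51 against 7.51 to 7.62), the cell cycle list (5.37 against 6.40 to 6.57), Csf3r (6.57 against 7.59 to 7.73), Tyms (5.34 against 6.40 to 6.56), Ube2c (5.10 against 6.19 to 6.29), Cdk1 (4.14 against 5.15 to 5.29), Mrc1 (5.53 against 6.15 to 6.19) and Cd86 (2.57 against 3.52 to 3.72) lower, and the Wnt list (5.41 against 4.73 to 4.83), Lrp5 (7.10 against 6.40 to 6.51) and Igsf3 (5.22 against 4.82 to 4.88) higher. Cartilage DPBS male replicate 4 stood higher for Mmp11 (4.40 against 3.12 to 3.32), Igf1 (7.01 against 6.11 to 6.20), Ibsp (10.52 against 9.79 to 9.83), Ccn4 (6.66 against 5.45 to 5.65) and Ctnnb1 (9.86 against 9.52 to 9.54). The cartilage CD31 female stood lower for Adamts4 (1.81 against 3.09 to 3.13) and Timp4 (2.23 against 2.78 to 2.84) and higher for Tnf (1.95 against 0.99 to 1.08). The remaining cartilage values were Col10a1 in DPBS male replicate 1 (4.49 against 3.61 to 3.72), the mural cell list in SVF male replicate 1 (7.25 against 7.50 to 7.54), and Igsf3 (5.01 against 4.87 to 4.88) and Slc39a10 (5.25 against 5.13 to 5.14) in CD31 male replicate 3.

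Fat pad values far from their group were the inflammatory (3.95 against 4.14 to 4.15) and lymphocyte lists (-0.22 against 1.03 to 1.06) in SVF male replicate 3, the angiogenic list in CD31 male replicate 4 (7.15 against 6.70 to 6.77), and the TGF-beta and BMP list in CD31 male replicate 3 (6.01 against 6.07 to 6.08). Single genes were Col14a1 in the SVF female (10.90 against 11.23 to 11.25), Col28a1 in DPBS male replicate 1 (6.07 against 6.96 to 7.13), Thbs2 in DPBS male replicate 3 (10.33 against 9.20 to 9.38), Myl9 in SVF male replicate 1 (8.26 against 8.76 to 8.85) and Tnf in the DPBS female (0.62 against -0.60 to -0.52).

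Effects that differed between the tissues, by the tested interaction, were for SVF 1 gene and the protease (-0.65), mural cell (-0.52) and immediate early lists (0.55). For CD31 they were 97 genes and the hypertrophy (-1.51), protease (-0.86), marrow (2.12), fibroblast (-1.39), bone (-1.56), immediate early (0.65), cell cycle (0.76) and TGF-beta and BMP lists (-0.54), all as log2 change in cartilage minus that in the fat pad, and all lists without a call when their correlation was estimated. Named genes were Nrep (-1.92), Creb3l1 (-1.76), Rcor2 (-2.21), Hsd11b2 (-2.07), Insc (-2.69), Myc (1.64), Ptger2 (0.996), Nt5c2 (0.63), Ptafr (1.06) and Hddc3 (0.58). The 97 calls depended on single libraries, as given with the results.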

How the results depend on the processing

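Tests chosen only after the result was seen were halved counts, the muscle and marrow covariates, leaving out 3 cartilage libraries, leaving out single libraries and voom for the 24-library results, and the exact permutation of list scores. Of 3869 values of 208 named gene results in the treatment comparisons, 3535 kept direction and side of the threshold, 11 lost a call, 232 gained one and 91 turned in direction. For the tissue contrast and interactions 1093 of 1250 kept both, 153 lost a call and 4 turned. Of 1139 values of the 61 list results past the threshold, 809 kept both, 321 lost the call and 9 turned. The protease list of cartilage after SVF kept its call under every alternative fit except camera with an estimated correlation, at means of -1.11 to -0.55. Its score differed by -1.06 (exact permutation p = 0.0286, the lowest that 70 relabellings can give). The immediate early list of the fat pad after CD31 kept its call under every alternative fit except camera with an estimated correlation and fry, at means of -1.54 to -0.93. Its score did not pass a permutation (difference -1.13, exact permutation p = 0.0857). Nrep, the named gene called in the fat pad after CD31, lost its call with no sex term, in males alone, in the fit by replicate number, without library numbers above 50, with the covariates and without 6 of the 8 libraries in turn, at log2 changes of 0.94 to 1.17 throughout. At 72628067 to 107619052 counts per library, halving the counts changed no count of calls by over 1.5 times.

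Counts of genes called that moved by over 1.5 times follow, with the reported count in parentheses, and the cause was not tested. DESeq2 called 715 for cartilage SVF against DPBS (0), 1401 for cartilage CD31 against DPBS (0), 14 for cartilage CD31 against SVF (0), 63 for fat pad SVF against DPBS (1), 204 for fat pad CD31 against DPBS (4), 220 for fat pad CD31 against SVF (0), 79 for the SVF interaction (1) and 1019 for the CD31 interaction (97). Voom with quality weights called 1050 for cartilage SVF against DPBS (0), 1770 for cartilage CD31 against DPBS (0), 1 for fat pad CD31 against SVF (0), 26 for the SVF interaction (1) and 1807 for the CD31 interaction (97). With no sex term edgeR called 120 for cartilage SVF against DPBS (0), 0 for fat pad SVF against DPBS (1), 0 for fat pad CD31 against DPBS (4) and 355 for the CD31 interaction (97). Males alone gave 341 for cartilage SVF against DPBS (0), 1 for cartilage CD31 against DPBS (0), 0 for fat pad SVF against DPBS (1), 5 for the SVF interaction (1) and 9 for the CD31 interaction (97). Without library numbers above 50 there were 0 for fat pad SVF against DPBS (1), 1 for fat pad CD31 against DPBS (4), 0 for the SVF interaction (1) and 3 for the CD31 interaction (97). With muscle and marrow scores as covariates there were 0 for fat pad SVF against DPBS (1), 0 for fat pad CD31 against DPBS (4), 5057 for cartilage against fat pad (13105), 5 for the SVF interaction (1) and 48 for the CD31 interaction (97). Without the 3 cartilage libraries there were 250 for cartilage SVF against DPBS (0) and 7 for the CD31 interaction (97), and with no filter on low counts 62 for the CD31 interaction (97). RLE size factors and halved counts moved none of them by that much. Leaving out 1 library at a time gave 0 to 302 for cartilage SVF against DPBS, 0 to 1 for cartilage CD31 against DPBS, 0 to 1 for cartilage CD31 against SVF, 0 to 3 for fat pad SVF against DPBS, 0 to 11 for fat pad CD31 against DPBS, 0 to 1 for fat pad CD31 against SVF, 12814 to 13391 for cartilage against fat pad, 1 to 3 for the SVF interaction and 0 to 994 for the CD31 interaction.

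Counts of lists past the threshold moved as follows, with the reported count in parentheses. No list passed in any comparison or interaction when camera estimated the correlation. Fry gave 2 for cartilage SVF against DPBS (10), 0 for cartilage CD31 against DPBS (11), 0 for cartilage CD31 against SVF (10), 0 for fat pad SVF against DPBS (7), 0 for fat pad CD31 against DPBS (1), 0 for fat pad CD31 against SVF (5), 21 for cartilage against fat pad (6), 1 for the SVF interaction (3) and 3 for the CD31 interaction (8). With no sex term there were 5 for cartilage SVF against DPBS (10), 2 for fat pad CD31 against DPBS (1) and 3 for fat pad CD31 against SVF (5). Males alone gave 0 for cartilage CD31 against SVF (10) and 2 for fat pad SVF against DPBS (7). Without library numbers above 50 there were 4 for cartilage SVF against DPBS (10) and 5 for the SVF interaction (3). The covariates, under which the muscle and marrow lists themselves have no value, gave 4 for cartilage SVF against DPBS (10), 1 for cartilage CD31 against DPBS (11), 4 for cartilage CD31 against SVF (10), 2 for fat pad SVF against DPBS (7), 3 for fat pad CD31 against DPBS (1) and 5 for the CD31 interaction (8), and leaving out the 3 cartilage libraries 5 for cartilage CD31 against SVF (10). For cartilage CD31 against SVF only 1 of the 4 and 2 of the 5 were among the reported 10. Leaving out 1 library at a time gave 4 to 11 for cartilage SVF against DPBS, 9 to 12 for cartilage CD31 against DPBS, 0 to 11 for cartilage CD31 against SVF, 1 to 8 for fat pad SVF against DPBS, 1 to 5 for fat pad CD31 against DPBS, 3 to 7 for fat pad CD31 against SVF, 6 to 8 for cartilage against fat pad, 0 to 9 for the SVF interaction and 5 to 9 for the CD31 interaction.

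Log2 changes that turned in direction are given from the reported to the alternative value, and the cause was not tested. No gene called in a treatment comparison was among them. Csf3r, Myh2, Tcap, Tnni2, Mybpc1 and Mybpc2 belong to the covariate scores, so their turns decide nothing. With the covariates: Mmp3 turned from -1.03 to 1.07, Csf3r from 0.56 to -0.14, Acan from -0.0752 to 0.36 and Tnf from 0.38 to -0.21 in cartilage SVF against DPBS. The cartilage matrix list turned from -0.87 to 0.0438, the cell cycle list from 0.65 to -0.11, Mmp3 from -1.42 to 0.9998, Myh2 from -1.78 to 0.0487, Cdk1 from 0.66 to -0.0137, Acan from -0.71 to 0.20, Col10a1 from -0.48 to 0.32 and Tnf from 0.70 to -0.13 in cartilage CD31 against DPBS. The cell cycle list turned from 0.27 to -0.12, the Wnt list (by camera's direction) from -0.36 to -0.00310, Cdk1 from 0.31 to -0.0144, Tcap from -1.34 to 0.0870, Tnni2 from -1.13 to 0.0390, Col2a1 from -0.40 to 0.45 and Adipoq from 0.0667 to -0.32 in cartilage CD31 against SVF. Mybpc2 turned from 3.27 to -0.18 and Mmp13 from 0.40 to -0.00300 in fat pad SVF against DPBS. Col10a1 turned from 0.00385 to -0.57 in fat pad CD31 against DPBS. Mybpc1 turned from -2.12 to 0.15 and Tnf from -0.0528 to 0.19 in fat pad CD31 against SVF. Edar turned from 5.37 to -0.89, Tubb1 from 5.32 to -0.25, Mmp13 from 3.63 to -0.38 and Adamts4 from -1.28 to 0.27 in cartilage against fat pad. The cell cycle list turned from 0.76 to -0.38 in the CD31 interaction. In males alone: the cell cycle list turned from 0.27 to -0.13, Cdk1 from 0.31 to -0.0222, Col2a1 from -0.40 to 0.32, Mmp3 from -0.38 to 0.25, Il1b from 0.19 to -0.12 and Tnf from 0.32 to -0.0831 in cartilage CD31 against SVF. Col2a1 turned from 0.0583 to -0.41 in fat pad SVF against DPBS. Adipoq turned from -0.0136 to 0.0147 and Col10a1 from 0.00385 to -0.34 in fat pad CD31 against DPBS. Without the 3 cartilage libraries: the cell cycle list turned to -0.14, Cdk1 to -0.0296, Col2a1 to 0.32, Mmp3 to 0.25, Il1b to -0.13 and Tnf to -0.0889 in cartilage CD31 against SVF. With voom and quality weights: Il1b turned from 0.19 to -0.0752 and Adipoq from 0.0667 to -0.10 in cartilage CD31 against SVF. Col2a1 turned from 0.0583 to -0.35, Col10a1 from -3.17 to 0.0420 and Mmp13 from 0.40 to -0.12 in fat pad SVF against DPBS. Adamts4 turned from -0.68 to 0.0365 in fat pad CD31 against DPBS. Without library numbers above 50: Acan turned from -0.0752 to 0.22 in cartilage SVF against DPBS. Col2a1 turned from 0.0583 to -0.35 in fat pad SVF against DPBS. Adipoq turned from -0.0136 to 0.0227 and Col10a1 from 0.00385 to -0.33 in fat pad CD31 against DPBS. With no sex term: Col2a1 turned from 0.0583 to -0.0709 in fat pad SVF against DPBS. In fat pad CD31 against DPBS, Col10a1 turned from 0.00385 to -0.00252 with RLE size factors, -0.000191 with no filter and -0.0850 with halved counts. The similarity of SVF and CD31 changes moved with split DPBS libraries from 0.670 to 0.352 in cartilage and turned from 0.328 to -0.141 in the fat pad, where the split removes the shared reference.

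Single libraries left out in turn also turned some log2 changes. Acan ranged from -0.37 to 0.20 in cartilage SVF against DPBS. Adipoq ranged from -0.21 to 0.81 in cartilage CD31 against DPBS. The cell cycle list ranged from -0.13 to 0.45, Cdk1 from -0.0218 to 0.48, Col2a1 from -0.77 to 0.32, Mmp3 from -0.62 to 0.25, Il1b from -0.12 to 0.29, Tnf from -0.0826 to 0.48 and Adipoq from -0.39 to 0.25 in cartilage CD31 against SVF. Adipoq ranged from -0.29 to 0.11, Col2a1 from -0.45 to 0.52, Acan from -1.62 to 0.40, Col10a1 from -4.12 to 1.01 and Mmp13 from -1.36 to 0.80 in fat pad SVF against DPBS. Adipoq ranged from -0.22 to 0.26, Adamts4 from -0.93 to 0.29 and Col10a1 from -1.15 to 4.57 in fat pad CD31 against DPBS. Adipoq ranged from -0.0368 to 0.22 and Tnf from -0.24 to 0.18 in fat pad CD31 against SVF.

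Pairing by replicate number was checked within a tissue only. Same-numbered libraries of different groups correlated in their deviations at -0.44 to 0.30 in cartilage (1 of 10 pairs above 0.1). In the fat pad this was -0.34 to 0.48 (7 of 10, mean 0.17 against -0.04 for other pairs), so pairing stayed open. With sex and replicate number as a replicate block, edgeR called 0 for fat pad SVF against DPBS (1), 0 for fat pad CD31 against DPBS (4) and 0 for the CD31 interaction (97), and the lists past the threshold numbered 3 for fat pad CD31 against DPBS (1). Under the block, Acan turned to 0.0354 in cartilage SVF against DPBS and Adipoq to -0.0728 in cartilage CD31 against SVF. In the fat pad Mmp13 turned to -0.44 (SVF against DPBS), Adipoq to 0.0436 (CD31 against DPBS) and Tnf to 0.0122 (CD31 against SVF).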

Other observations

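In the fat pad, scores of the cartilage matrix list stood above every DPBS library in all 4 CD31 libraries, though the list did not pass against DPBS after adjustment. The exact permutation of list scores, chosen only after the result was seen, gave a difference of 1.16 log2 units between CD31 and DPBS (exact permutation p = 0.0286, the lowest that 70 relabellings can give). Against SVF the difference was 1.30 (exact permutation p = 0.0286). Snorc stood at 0.431 ± 0.525 CPM after CD31, 0.114 ± 0.126 after DPBS and 0.204 ± 0.111 after SVF. Comp was level with DPBS, at 1097 ± 141, 1072 ± 760.4 and 669 ± 401. For interferon response genes the difference between CD31 and SVF in the fat pad was -0.52 (exact permutation p = 0.0286). Over all 6 treatment comparisons, 22 of 138 list tests reached the lowest p possible. With 70 relabellings an adjustment over 23 lists can go under 0.05 only when most lists reach that p, so the adjusted values decide nothing and none of these differences is called.

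Other splits of the same 8 libraries into 4 and 4 often gave as many calls as the real groups, counted with the real split included. In cartilage after SVF, as many came from 4 of 35 (real count 2144, highest other 5402) for edgeR genes at an unadjusted p under 0.05, 3 of 35 (real count 715, highest other 3247) for DESeq2 genes and 6 of 35 (real count 10, highest other 11) for lists, so chance was not excluded for any of these. An edgeR count of 0 at an adjusted p under 0.05 is reached by every split (35 of 35) and decides nothing. This holds here and for fat pad CD31 against SVF (highest other 1), and for cartilage CD31 against DPBS and SVF (highest other 0). For cartilage SVF against DPBS the highest other DESeq2 count was several times the real one, and what set that split apart was not tested. For cartilage CD31 against DPBS the counts were 2 of 35 (real count 4144, highest other 4511) for unadjusted edgeR genes and 5 of 35 (real count 11, highest other 16) for lists, and chance was not excluded for these. For the DESeq2 genes no other split reached the real count, at 1 of 35 (real count 1401, highest other 345). That is the lowest share 35 splits can give. The shares were not adjusted over the counts tested, so chance was not excluded there either. Between CD31 and SVF in cartilage they were 10 of 35 (real count 847, highest other 3566) unadjusted, 9 of 35 (real count 14, highest other 310) for DESeq2 and 3 of 35 (real count 10, highest other 12) for lists, and chance was not excluded.

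Fat pad splits after SVF gave 5 of 35 (real count 1, highest other 4) for edgeR genes, 7 of 35 (real count 1495, highest other 3099) unadjusted, 9 of 35 (real count 63, highest other 1145) for DESeq2 genes, again several times the real count, and 8 of 35 (real count 7, highest other 11) for lists. After CD31 they gave 2 of 35 (real count 4, highest other 6), 4 of 35 (real count 1600, highest other 2205) unadjusted, 4 of 35 (real count 204, highest other 586) for DESeq2 and 31 of 35 (real count 1, highest other 9) for lists, so chance was not excluded in either comparison. Between CD31 and SVF fat pads no other split reached the real count of genes at an unadjusted p under 0.05, at 1 of 35 (real count 1727, highest other 1252). This is again the lowest share possible, unadjusted over the counts tested, so chance was not excluded. Nor was it for DESeq2 genes (2 of 35 (real count 220, highest other 238)) or lists (15 of 35 (real count 5, highest other 10)). Of 100 regroupings of the 24 libraries, chance was excluded for the tissue contrast, at 1 of 100 (real count 13105, highest other 9810). For the CD31 interaction the share was 2 of 100 (real count 97, highest other 468), where the highest other count was several times the real one. That share was not adjusted over the counts tested, and the real count depended on single libraries, so chance was not excluded there. Nor was it for the SVF interaction, at 10 of 100 (real count 1, highest other 17).

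On the first 2 principal components of cartilage (39.0 and 16.2 percent of variance) DPBS male replicate 4 lay at -84.1 and 47.2, the SVF female at -57.8 and -70.8 and the CD31 female at 80.2 and 4.25. In the fat pad (28.96 and 16.9 percent) DPBS male replicate 3 lay at 66.5 and 12.3.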
